A study of Mus musculus with 57 samples.

How the data were processed

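The measured material was astroglial RNA from mouse cerebral cortex, obtained by translating ribosome affinity purification (TRAP). The mice carried the ribosomal protein L10 fused to green fluorescent protein (GFP) under the control of Aldh1l1, a gene of astrocytes, on a C57BL/6 background. Per the labels' protocols, cycloheximide held the ribosomes on their messages, tagged polysomes were pulled out of cortical homogenate with an antibody to GFP, poly(A) RNA was selected with oligo-dT beads, and strand-marked libraries were prepared from RNA with an integrity number above 8. The labels name 53 animals in 12 groups of sex and age, at P1, P4, P7, P14, P35 (postnatal days) and in adults. Groups held between 3 and 8 libraries.

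The deposited values are whole-number counts per gene, not normalized, in 1 table of 21118 genes and 53 columns, each column with its own animal. Reads were processed with CASAVA, HISAT2, SAMtools and featureCounts on the mouse build GRCm38.p5, per the submitters' processing notes, which give no versions. The gene annotation release, the strand setting of the counting and any gene filter are not given in the sources used here. The lowest row total was 50 counts and the fewest libraries with a count for any gene was 6, so genes of lower abundance were not analysed here. Total counts per library ran from 14768178 to 48541139 with a median of 24033399. Of the animals, 4 at P7 (females 6 and 10, males 2 and 6) were sequenced in 2 runs per the labels, and each has 1 column with a total of at least 42222297 counts, which was used as it stands, so the planned variants on separate runs of these animals were not run. Another 4 libraries at P7 (females S1 and S2, males S1 and S2) came from the second run alone.

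Gene positions came from GENCODE release M21 on GRCm38, in which 21033 of the 21118 gene identifiers (99.6%) were found, 20207 of them with the same symbol. Reads of overlapping genes, of antisense partners and of near-identical copies cannot be told apart without the counting rule, so values of Gm29650, of Ifit3 beside Ifit3b and of ribosomal proteins with pseudogene copies are uncertain.

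Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, robust dispersion estimates and the quasi-likelihood F test) in 1 model of all 53 libraries with the 12 groups and the sequencing run (second run alone against the rest) as terms. Libraries of the second run alone occur at P7 only, so the run term is estimated within that age. All adjusted p-values of genes are Benjamini-Hochberg values over the 21118 genes tested in a comparison, with a threshold of 0.05, and standard errors are on the log2 scale. The edgeR filter on low counts removed 0 genes. The comparisons were females minus males at each age and as a mean over the 6 ages, each step from one age to the next within a sex, P1 to adult as the mean of the sexes, and the difference between the sexes in each step (interaction), alone and as 1 test over all steps. Levels are given as CPM, counts scaled to a common library total, on TMM-scaled library sizes, as mean ± SD over libraries. Excepted are levels of sex-linked genes and of Aldh1l1 in single libraries, which are CPM of the total count. Fitted fold changes of genes with few counts depend on the prior count, and where a side had no more than 3 counts in all, a bound against 3 counts over that side is given. Bounds cover counting error only.

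In all, 30 gene lists fixed before the data were examined (astrocyte functions, markers of other cell types, sex-linked genes, immediate early genes, mitochondrially encoded genes) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted within a comparison, and again with the correlation estimated per list. After the data were examined, list calls were also tested with each library of the compared groups left out in turn. A list needed 5 measured members. A list score is the mean log2 CPM of its members (prior count 2). Over 23 signed comparisons, 258 of 690 tests passed at the preset correlation and 14 with an estimated correlation. Those 14 are named where they occur, and all other list calls in these comparisons hold at the preset correlation only.

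Genes named in the text follow a rule written before the data were examined. In each sex difference and step, up to 6 genes in each direction (10 for P1 to adult) were taken by the size of the fold change among those past the threshold, with a mean of at least 5 CPM on the higher side and no overlap between the libraries of the compared groups. Predicted genes were left out. Sex chromosome genes were counted apart. Of each list, up to 4 members were named by the smallest adjusted p, or by the highest mean where no member passed. Genes outside the rule are said to be chosen after their values were seen.

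The number at the end of a library's description name (1, 2, 3, 4 or 6) is shared between groups, and libraries of the second run alone were taken as a level of their own. Most libraries with the same number deviated from their group means in the same direction. Over 14738 genes, the median correlation of deviations was 0.49 in 223 pairs of libraries with the same level from different groups and -0.13 in other pairs, with -0.15 as the lowest value within a level, between P14 male 6 and P7 male 6. In the 10 comparisons with at least 3 pairs of the same replicate number every pair correlated above 0.1 (lowest 0.16), so these numbers were taken to pair the libraries. What the number stands for is not given in the sources used here. A second fit with this number as a block (in place of the run term) was planned before the data were examined, and its value is printed beside a result where it changes the call or moves a count by more than 1.5 times. The block left 36 residual degrees of freedom in place of 40 and lowered the common biological coefficient of variation from 70.4% to 53.2%.

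Further alternatives were DESeq2 size factors in the edgeR fit, DESeq2 1.42.0, limma voom with quality weights, no low-count filter, no run term, libraries without the second run, the compared groups alone, 5 libraries left out whose description name carries the letter of the other sex, and each library left out in turn. After the data were examined, further alternatives left out 6 libraries whose sex-linked genes go against the label, P7 male 6 and P14 male 6, and the 3 libraries with the fewest genes at 10 counts or more, and all 11 of these with the block, or used 3 levels of run or a minimum mean of 1 CPM. The edgeR, voom, DESeq2 and camera steps were tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes per comparison. From P1 to P4 in males, edgeR recovered 26.0% of genes changed 4-fold and 72.0% of those changed 8-fold with 1 false call among 20615 genes. From P1 to adult it recovered 12.0% of genes changed 2-fold, 70.0% of those changed 4-fold and 92.0% of those changed 8-fold with 9 false calls. In these comparisons voom made 4 and 8 false calls and DESeq2 30 and 32, which limits what the DESeq2 counts in the text show. The simulated libraries were drawn independently, without shared deviations of a description number and without correlation between genes. Recovery and false calls in the real libraries may therefore differ from these values. All libraries were kept in the groups that the title, source name and sex tag give.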

Results

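Ribosome-bound messenger RNA of cortical astroglia was measured in 53 libraries, 1 for each animal, from male and female mice between the first postnatal day and adulthood. The groups labelled female held 4 libraries at P1, 4 at P4, 8 at P7, 5 at P14, 3 at P35 and 4 in adults. The groups labelled male held 4, 4, 4, 5, 3 and 5 libraries at these ages. The design asks how the messages that astroglia translate change with age in each sex, and whether the sexes differ. Total counts ran from 14768178 in P14 male 4 to 48541139 in P7 female 6. P1 female 4 had at least 10 counts in 10085 genes, P7 female 40 in 13834 and P14 male 4 in 14530, against 15531 or more in all other libraries. Aldh1l1, the gene whose promoter drives the tagged ribosomal protein, stood at 8.88 CPM in P1 female 4 and between 34.2 and 377 CPM in the others. The 100 most abundant genes took 38.3% of the counts in P14 male 4 and from 14.3 to 25.4% elsewhere.

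Sex-linked transcripts were examined first, since they check the labels. Xist is the RNA that silences an X chromosome, and Ddx3y, Eif2s3y, Kdm5d and Uty lie on the Y chromosome. Of the 25 libraries labelled male, 20 held between 73.1 and 223 CPM of the 4 Y-linked genes together. P4 male 4 (0.501 CPM), P35 male 10 (0.171 CPM) and adult male 60 (0.0933 CPM) held far less, and P7 male S2 had no count of them, which allows up to 0.140 CPM. Xist in these 4 libraries stood at 10.6, 43.2, 3.33 and 20.7 CPM in the same order, and in the 20 others at no more than 0.973 CPM. Conversely, P4 female 2 held 60.8 CPM and P7 female S2 held 194 CPM of the Y-linked genes, with no count of Xist, which allows up to 0.141 and 0.139 CPM. In a middle range of the Y-linked sum were P14 male 4 (17.2 CPM), P7 female 30 (17.7 CPM), adult female 3 (7.96 CPM), adult female 2 (5.67 CPM), P7 female 10 (3.84 CPM) and P7 female 40 (1.90 CPM). The remaining 21 libraries labelled female held at most 0.965 CPM, with Xist anywhere from 0.0621 to 125 CPM. The description names of 5 libraries carry the letter of the other sex, namely P7 females 10, 30 and 40, P35 male 10 and adult male 60. All libraries stayed in the groups their labels give, so each direction below that involves sex is one between labelled groups.

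**Figure D1:**
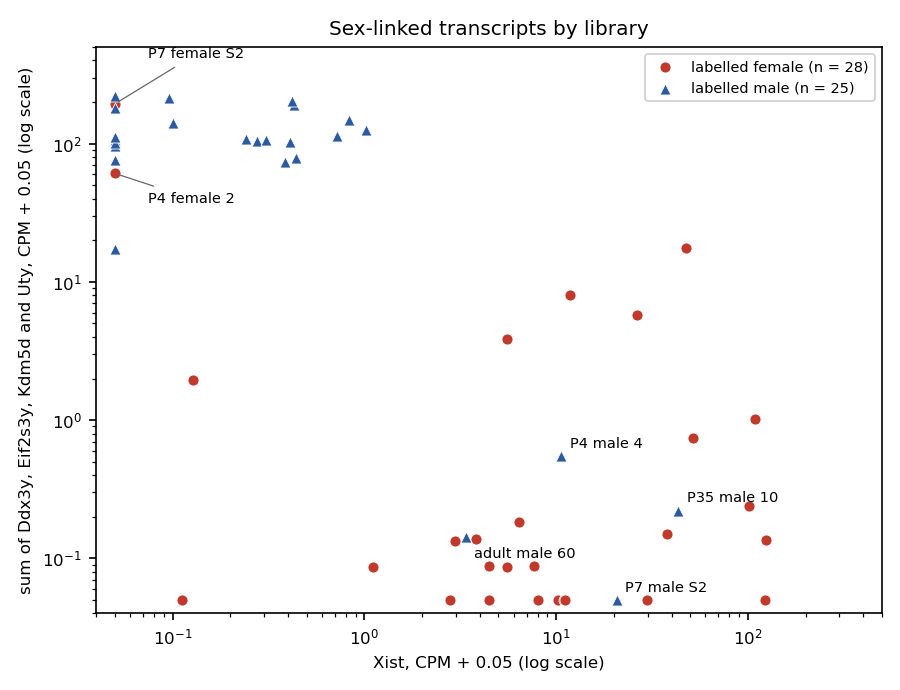
Each point is 1 of 53 libraries, with Xist on the horizontal axis and the sum of Ddx3y, Eif2s3y, Kdm5d and Uty on the vertical axis, both in CPM plus 0.05 on log scales. The 6 libraries named in the plot lie among those of the other label, for example P7 female S2 at 194 CPM of Y-linked genes and P35 male 10 at 43.2 CPM of Xist.

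Markers of neurons and of mature astrocytes moved against each other between libraries of different description numbers. Compared with number 1 and with sex and age in the model, libraries of number 6 were higher in 29 of 32 neuronal markers (median log2 difference 1.82) and lower in 28 of 28 mature astrocyte markers (median -2.67). Libraries of number 3 were higher in 31 neuronal markers (median 1.76) and lower in 26 mature astrocyte markers (median -1.79). Those of the second run alone were higher in 25 neuronal markers (median 1.73), and their mature astrocyte markers had a median of -2.05. Other lists moved too. In number 3, 40 of 44 cytosolic ribosomal proteins were lower and 10 of 13 mitochondrially encoded genes higher, and in the second run 29 ribosomal proteins were lower. In number 4, 42 ribosomal proteins and 13 neuronal markers were higher, and 2 neuronal and 14 mature astrocyte markers lower. Number 2 had 0 genes past the threshold, but lists moved by camera at the preset correlation. Mature astrocyte markers were lower (median -0.67, adjusted p = 2.37e-20, and 0.0838 with an estimated correlation). Cytosolic ribosomal proteins were higher (median 0.33, adjusted p = 4.17e-18, and 0.192 with an estimated correlation). For number 6 the adjusted p was 0.00506 for the neuronal and 0.0134 for the astrocyte list with an estimated correlation, for number 3 it was 0.0379 for the neuronal and 0.279 for the astrocyte list, and for the second run 0.0623 and 0.440, so both lists passed with that estimate in number 6 alone. In edgeR, 14585 of 21118 genes differed between the numbers. A group's libraries are spread over these numbers, and age or sex comparisons below that share few numbers carry part of this spread.

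**Figure D2:**
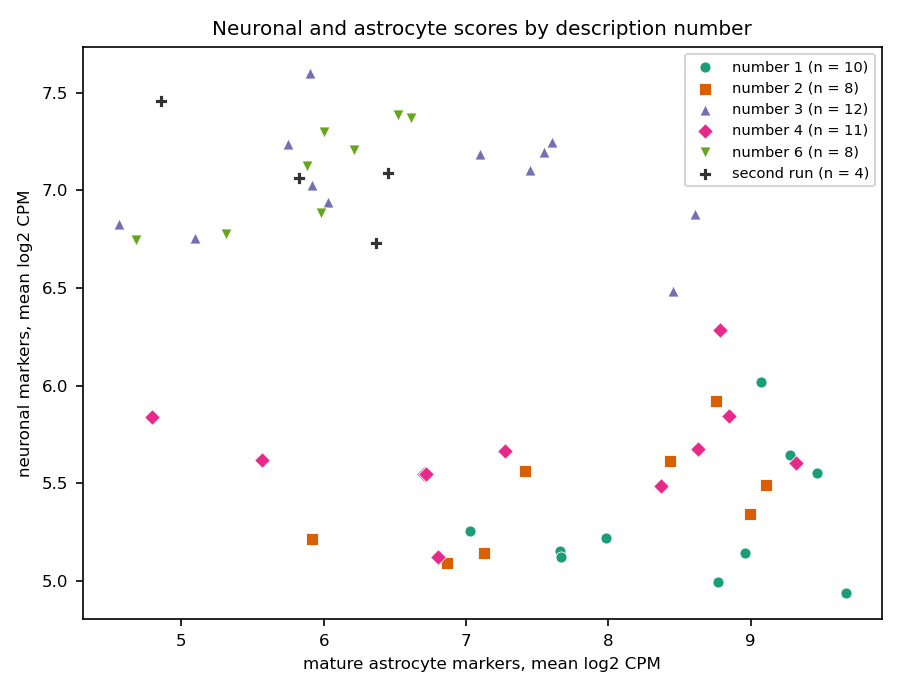
Each point is 1 library, with the mean log2 CPM of the mature astrocyte markers on the horizontal axis and that of the neuronal markers on the vertical axis, marked by description number. Libraries of numbers 3 and 6 and of the second run lie above the rest on the neuronal axis. With sex and age in the model, their neuronal scores were 1.75, 1.80 and 1.67 above number 1 in log2.

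From P1 to adulthood, as the mean of the sexes, genes of mature astrocytes rose. Of the 28 mature astrocyte markers, 23 rose and none fell (25 rose when adjusted over the list alone), with a median log2 change of 2.32. S100b, a calcium-binding protein of astrocytes, went from 21.4 ± 25.4 CPM (SD, n = 8) at P1 to 1040 ± 517 CPM (n = 9) in adults, a log2 change of 5.71 ± 0.70 (SE, adjusted p = 3.59e-08). Gjb6, which encodes the gap junction protein connexin 30, went from 15.0 ± 14.3 to 279 ± 176 CPM (log2 4.32 ± 0.64, adjusted p = 1.52e-06), and the glycolytic enzyme gene Aldoc from 649 ± 430 to 6610 ± 3300 CPM (log2 3.37 ± 0.51). The largest rise among genes named by rule was that of Etnppl (ENSMUSG00000019232, chromosome 3, 130617448 to 130637521 on GRCm38), an enzyme of phosphoethanolamine breakdown, from 0.447 ± 1.09 to 68.6 ± 34.8 CPM (log2 8.90 ± 1.24, adjusted p = 4.26e-07). Of 24 genes of transmitter uptake and ion transport, 15 rose and 1 fell (17 and 1 adjusted over the list alone, median 1.36, and 2.16 without P1 female 1). Slc1a2, the main glutamate transporter of astrocytes, went from 80.1 ± 87.6 to 1100 ± 359 CPM, and Glul, which makes glutamine from glutamate, from 194 ± 129 to 2210 ± 1210 CPM. The tests of these lists by camera gave adjusted p = 2.26e-15 for the astrocyte markers (0.229 with an estimated correlation, 0.0277 with the block) and 4.71e-09 for transport (0.265 with an estimated correlation). The neuronal markers split, with 12 of 32 up and 10 down and a median of 0.13. In all, 5926 of 21118 genes changed (edgeR, adjusted p under 0.05), 3088 upward and 2838 downward.

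Genes of cell division fell over the same span. All 32 cell cycle genes fell, with a median log2 change of -3.92 (camera adjusted p = 1.47e-32, and 0.00448 with an estimated correlation). Cdk1 (ENSMUSG00000019942, chromosome 10, 69335146 to 69352938), the kinase that drives entry into mitosis, went from 58.4 ± 18.6 CPM (n = 8) to 1.01 ± 0.856 CPM (n = 9), a log2 change of -5.84 ± 0.61 (adjusted p = 1.05e-09). Ccna2 fell by 5.11 and Nusap1 by 4.09 on the log2 scale, and Chaf1b, a subunit of the complex that places histones on new DNA, by 6.05. The radial glia and neural progenitor markers went both ways, with 3 of 25 up and 8 down (4 and 9 adjusted over the list alone, 6 and 9 with the block, median -0.14, adjusted p = 0.00514, and 0.575 with an estimated correlation). Their median was 0.15 without P1 female 1, -0.27 without P1 female 6, -0.07 without P1 male 1, -0.05 without adult female 3 and -0.04 without adult male 60. Among those that fell were the transcription factor genes Sox11 (log2 -4.48 ± 0.38) and Sox4 (-3.58 ± 0.26), Nes (-4.33 ± 0.45) and Fabp7, from 11400 ± 7050 to 749 ± 464 CPM. Further genes named by rule fell. Cd24a (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265) went from 615 ± 237 to 7.67 ± 4.54 CPM (log2 -6.33 ± 0.56, adjusted p = 2.61e-11), Dcx, a microtubule protein of migrating neurons, from 666 ± 436 to 14.4 ± 16.1 CPM, and St8sia2, which builds polysialic acid, from 45.4 ± 31.6 to 0.772 ± 0.676 CPM. Also named by rule were Igfbpl1 (log2 -6.20), Trim67 (-6.02), Vash2 (-5.48) and Akr1c19 (-7.88). P2rx2, an ion channel opened by ATP, had no count in the 9 adult libraries against 5.93 ± 7.69 CPM at P1, at least 409-fold lower against a floor of 3 counts over the adult group.

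Metabolic genes shifted in the same comparison. Of 27 genes of glycolysis, lactate and glycogen, 19 rose and none fell (19 adjusted over the list alone, median 1.16, adjusted p = 1.39e-11, and 0.0329 with an estimated correlation, a call lost without P1 female 1 or, at 0.0524, without P1 female 6). Aldoa went from 567 ± 144 CPM (n = 8) to 2780 ± 1050 CPM (n = 9), a log2 change of 2.31 ± 0.25, Tpi1 from 421 ± 142 to 1280 ± 274 CPM, and Pygm, the glycogen phosphorylase of muscle and brain, from 4.26 ± 2.89 to 62.2 ± 22.9 CPM (log2 3.86 ± 0.51). In fatty acid oxidation, 7 of 20 rose and 2 fell (10 and 2 adjusted over the list alone, 12 and 2 with the block, median 0.73, adjusted p = 0.0635, and 0.0392 with the block, which was 0.635 with an estimated correlation). Hadhb was among those that rose (log2 1.85). Of the nuclear encoded respiratory chain, 10 of 31 rose and none fell (adjusted p = 0.00133, and 0.476 with an estimated correlation), and 24 rose with the block. Of 44 cytosolic ribosomal proteins, 16 fell and none rose (median -0.76, adjusted p = 1.26e-06, and 0.601 with an estimated correlation), and 34 fell with the block. Rplp0 had a log2 change of -1.32 ± 0.34 and Rpl5 of -1.03 ± 0.22. In cholesterol synthesis 6 of 23 fell and none rose, among them Lss (log2 -1.44 ± 0.27) and Hmgcs1 (-1.40 ± 0.35), while the list as a whole had adjusted p = 0.0741. No member of the 13 mitochondrially encoded genes passed (median 0.28, adjusted p = 0.760).

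Genes that respond to glucocorticoids rose with age. Of the 22 glucocorticoid responsive genes, 14 rose and none fell (15 and 1 adjusted over the list alone, 16 and 2 with the block, median 1.65, adjusted p = 5.36e-07, and 0.00694 with an estimated correlation). Klf9 went from 81.4 ± 48.1 CPM (n = 8) to 500 ± 165 CPM (n = 9), a log2 change of 2.60 ± 0.32 (adjusted p = 3.32e-08). The glucocorticoid receptor gene Nr3c1 rose by 1.71 ± 0.25 and the mineralocorticoid receptor gene Nr3c2 by 2.11 ± 0.38 on the log2 scale. Of 25 immediate early genes, which respond within minutes to cell stimulation, 12 rose and none fell (14 adjusted over the list alone, median 1.06, adjusted p = 4.84e-05, and 0.229 with an estimated correlation). Arc went from 7.65 ± 2.49 to 167 ± 138 CPM, Junb from 11.1 ± 6.73 to 127 ± 103 CPM, and Fos from 9.40 ± 7.10 to 86.5 ± 69.2 CPM.

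Markers of other cells of the cortex also changed between P1 and adulthood. All 19 oligodendrocyte and myelin markers rose (median log2 3.66, adjusted p = 2.33e-15, 0.0329 with an estimated correlation and 0.0509 with that estimate and the block). The estimate also missed the threshold without P1 female 1, P1 male 3 (0.0505), P1 female 6 (0.0524) or P1 female 3 (0.0583). Mobp (ENSMUSG00000032517, chromosome 9, 120149707 to 120181484), a protein of compact myelin, went from 1.65 ± 2.32 CPM (n = 8) to 169 ± 97.2 CPM (n = 9), a log2 change of 6.65 ± 1.01 (adjusted p = 2.32e-06), and Opalin from 0.135 ± 0.245 to 14.6 ± 12.5 CPM. Pvalb, a calcium buffer of a class of inhibitory neurons, went from 0.641 ± 0.498 to 74.0 ± 92.2 CPM. Of 22 microglia and macrophage markers, 4 rose and none fell (3 adjusted over the list alone, adjusted p = 0.0245, 0.575 with an estimated correlation, 0.0608 with the block and 0.0579 without adult male 60), at low levels such as 5.09 ± 2.41 CPM for Tmem119 and 7.14 ± 2.40 CPM for P2ry12 in adults. These rises stand beside those of the astrocyte lists in the same libraries. Further genes named by rule were Rpe65 (log2 8.53), Igfn1 (8.17), Zfp831 (7.95), Cntnap1 (6.10), Tcap (5.97) and Wnt10a (5.90).

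**Figure D3:**
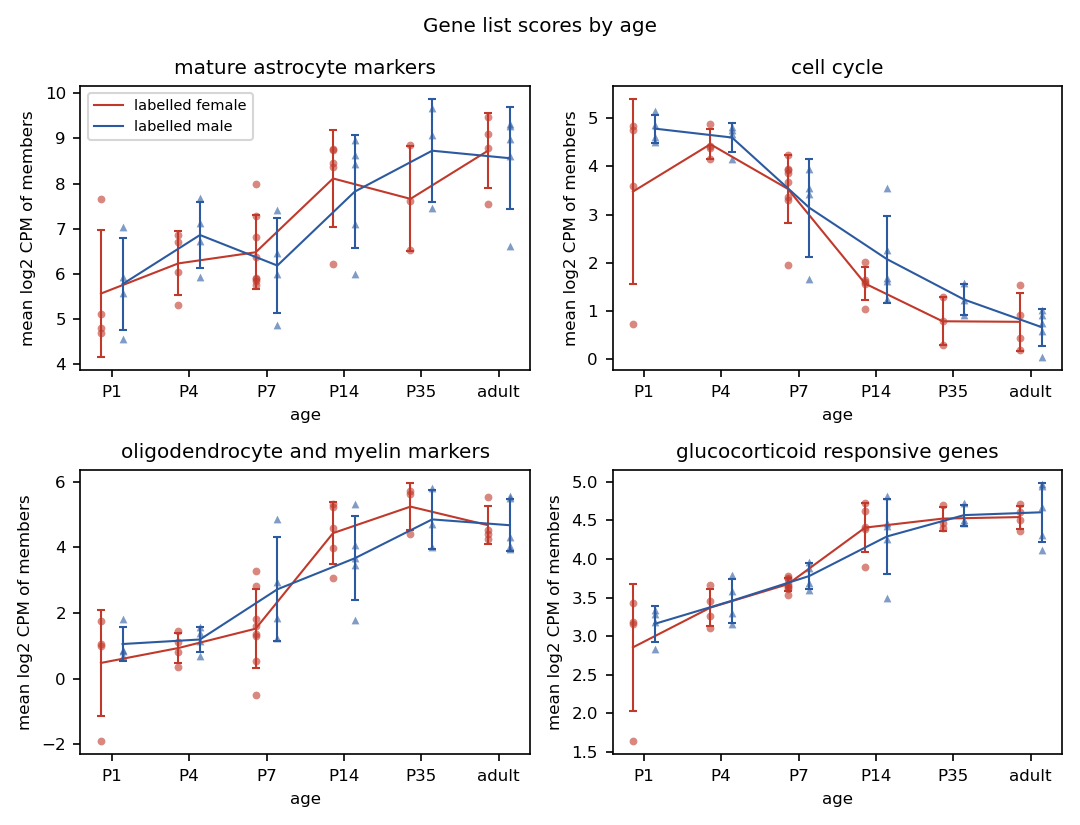
The mean log2 CPM of the members of 4 gene lists is plotted against age, with 1 point per library, and lines and bars for the mean and SD of each labelled sex. From P1 to adulthood the median log2 change of the members was 2.32 for mature astrocyte markers, -3.92 for cell cycle genes, 3.66 for oligodendrocyte and myelin markers and 1.65 for glucocorticoid responsive genes.

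Among the steps between neighbouring ages, that from P7 to P14 in animals labelled female held the most calls in edgeR with all libraries. In it, 123 genes changed, 63 upward and 60 downward. Etnppl went from 0.199 ± 0.238 CPM (n = 8) to 25.4 ± 25.3 CPM (n = 5), a log2 change of 6.75 ± 1.17 (adjusted p = 0.00257), and Gjb6 from 12.5 ± 9.67 to 241 ± 129 CPM (log2 3.98 ± 0.70, adjusted p = 0.00327). Slc1a2 rose by 2.11 ± 0.52 on the log2 scale. Etnppl and Gjb6 were the 2 of 28 mature astrocyte markers that passed (8 adjusted over the list alone, median 1.19, adjusted p = 3.77e-13, and 0.371 with an estimated correlation). Of 32 cell cycle genes 6 fell (29 adjusted over the list alone, median -1.91, adjusted p = 2.14e-27, and 0.00945 with an estimated correlation), among them Aurkb, a mitotic kinase gene, from 15.5 ± 10.6 to 1.05 ± 0.531 CPM (log2 -3.85 ± 0.87), and Cdk1 from 27.8 ± 11.4 to 4.02 ± 2.75 CPM. Of 19 oligodendrocyte and myelin markers 4 rose (16 adjusted over the list alone, median 2.23, adjusted p = 2.07e-22, and 0.0113 with an estimated correlation), for example Mobp from 9.08 ± 10.3 to 229 ± 116 CPM and Opalin from 0.121 ± 0.222 to 6.62 ± 4.13 CPM. Of 22 glucocorticoid responsive genes 2 rose (5 adjusted over the list alone and 6 with the block, median 0.52, adjusted p = 0.000136, 0.0436 with an estimated correlation and 0.0848 with that estimate and the block), namely Gjb6 and Sult1a1 (log2 3.14 ± 0.48). With an estimated correlation this list passed in 5 and missed the threshold in 8 of the 13 fits with 1 library left out, namely those without P14 females 3 or 4 or P7 females 3, 4, 6, 10, 30 or S1 (highest 0.0973, with a median of 0.30, without P14 female 4).

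Among the falls named by rule in the same step, Dpysl3 went from 1910 ± 1290 CPM (n = 8) to 90.9 ± 58.5 CPM (n = 5), a log2 change of -3.79 ± 0.80 (adjusted p = 0.0143), Dpysl5 from 601 ± 489 to 34.9 ± 28.3 CPM, and Trim67 from 154 ± 129 to 5.64 ± 2.62 CPM. Sla (log2 -3.05) and the DNA helicase gene Pif1 (-3.93) fell as well. Further rises were those of Rpe65 (log2 5.64), Pvalb (4.66), Kcng4 (4.56) and Kirrel2 (4.50). With the description number as a block, 1149 genes changed, 575 upward and 574 downward, with 13 mature astrocyte markers and 14 oligodendrocyte and myelin markers up and 17 cell cycle genes down. With DESeq2 size factors in place of TMM, 115 genes changed, and the share of upward changes was 63.5% in place of 51.2%. Leaving out P14 female 2 left 14 genes, P14 female 4 left 33, P7 female 6 left 46, P14 female 3 left 56, P7 female 30 left 63 and P14 female 1 left 66. Without the 5 libraries whose description letter is that of the other sex, 3 of which are P7 females, 3 genes passed the threshold, fewer than the 9 from P4 to P7 in males, and without the 11 libraries of doubtful sex, age or gene number the blocked fit called 3407 genes.

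No gene passed in the other steps of animals labelled female without the block. In edgeR the counts at an unadjusted p under 0.05 were 799 from P1 to P4, 558 from P4 to P7, 780 from P14 to P35 and 419 from P35 to adult, and DESeq2 called 21, 4, 10 and 2 genes in these steps, while voom called none. With the block, Myc, a growth-promoting transcription factor gene (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374), fell from P14 to P35, from 30.4 ± 14.1 CPM (n = 5) to 5.60 ± 2.29 CPM (n = 3), with a log2 change of -2.53 ± 0.46 (adjusted p = 0.0257, and 0.204 without the block). Marcksl1 was the other call (log2 -1.66 ± 0.31, adjusted p = 0.0257) and was chosen after its values were seen.

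In animals labelled male, 20 genes changed from P1 to P4 in the fit with the block, 12 upward and 8 downward. The neuronal transcription factor gene Neurod2 (ENSMUSG00000038255, chromosome 11, 98325415 to 98329648) went from 197 ± 52.6 CPM (n = 4) to 57.3 ± 33.1 CPM (n = 4), a log2 change of -1.99 ± 0.33 (adjusted p = 0.00564). Sox11 (log2 -1.96 ± 0.41), Scrt2 (-1.98), Rcor2 (-1.74), Cirbp (-1.50) and Dlx1 (-1.44), a homeobox gene of inhibitory neurons, fell with it. Dbx2 rose from 36.4 ± 16.7 to 176 ± 93.0 CPM (log2 2.30 ± 0.44, adjusted p = 0.0187), as did Dbndd2 (1.24), Tmem191c (1.13) and Rgs7 (1.04). Among the other rises, chosen after their values were seen, were Gfap, the intermediate filament of astrocytes, from 251 to 899 CPM (log2 1.90 ± 0.38, adjusted p = 0.0187), and Gpr37l1 (2.50 ± 0.50). Without the block no gene passed in edgeR (adjusted p = 1 for Neurod2), 423 genes had an unadjusted p under 0.05, and DESeq2 called 1 gene and voom 435.

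From P4 to P7 in animals labelled male, 4 genes rose without the block. Il34 (ENSMUSG00000031750, chromosome 8, 110741829 to 110805924), a ligand of the receptor that microglia need, went from 2.93 ± 0.614 CPM (n = 4) to 11.5 ± 8.63 CPM (n = 4), a log2 change of 2.64 ± 0.52 (adjusted p = 0.0486). Of these 4 P7 males, S1 and S2 come from the second run and are adjusted by the run term. Fitted changes in this step therefore lean on P7 males 2 and 6 and can differ from the ratio of the means. Mtfp1, a gene of mitochondrial fission, rose by 1.82 ± 0.35 (adjusted p = 0.0462). The other calls, Mobp (from 1.15 to 125 CPM) and Prss22 (to 1.92 CPM, at least 69.8-fold against a floor of 3 counts over the 4 libraries of P4), were chosen after their values were seen. With the block, 12 genes rose and 3 fell, among them Arpp21 (log2 1.52 ± 0.33) and Sox12 (-1.51 ± 0.32). The cell cycle list had a median of -1.53 with no member past the threshold (adjusted p = 6.24e-22, 0.0291 with an estimated correlation and 0.125 with that estimate and the block, and 0.0644 without P7 male 2 and 0.0784 without P7 male 6). These calls rest on P7 male 6 in part. Without it no gene passed, and its scores were 4.85 for the oligodendrocyte and myelin markers and 1.66 for cell cycle genes, against 1.80 and 3.55 in P14 male 6, an order of the ages opposite to that of P7 female 6 (1.81 and 3.37) and P14 female 6 (4.61 and 1.64). Leaving out any of P4 males 1, 2, 3 and 4 also left no gene, leaving out P7 male S1 left 1, P7 male S2 12 and P7 male 2 58.

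Later steps in animals labelled male held no call without the block. The step from P7 to P14 includes P7 male 6 and P14 male 6. Of the 123 genes called in this step in females, 4.07% changed the same way from the first of these libraries to the second. With each library left out in turn the count in males stayed at 0. The lack of calls therefore does not show that males changed less than females from P7 to P14. In edgeR, 553 genes from P7 to P14, 1117 from P14 to P35 and 284 from P35 to adult had an unadjusted p under 0.05, while DESeq2 called 1, 14 and 0 genes and voom 0, 146 and 81. From P14 to P35 the block gave 8 genes, all lower at P35. Myc went from 43.9 ± 20.8 CPM (n = 5) to 8.39 ± 1.70 CPM (n = 3), a log2 change of -2.41 ± 0.46 (adjusted p = 0.0347, and 0.269 without the block), and Marcksl1, a protein of actin-rich protrusions, from 1040 ± 622 to 232 ± 82.4 CPM (log2 -1.73 ± 0.31). Ppp1r14c (-1.61 ± 0.33) and Deaf1 (-1.17 ± 0.24) fell as well. Without the 11 libraries of doubtful sex, age or gene number, which leaves 3 males at P14 and 2 at P35, the blocked fit called 0 genes in this step, with 1196 at an unadjusted p under 0.05. From P7 to P14, the same fit called 96 genes, 31 upward and 65 downward, with 2 libraries left at P7.

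Between animals labelled female and male, the calls as a mean over the 6 ages were 5 sex chromosome genes. Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629) stood at 5.44 ± 20.4 CPM (n = 28) in libraries labelled female and 52.1 ± 34.0 CPM (n = 25) in those labelled male, a log2 difference of -6.87 ± 1.02. Eif2s3y (-6.62 ± 0.95), Uty (-6.65 ± 1.04) and Kdm5d (-5.94 ± 0.97, adjusted p = 0.00121) were lower in the same direction. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254) was higher, with 25.3 ± 36.4 against 3.26 ± 9.10 CPM (log2 4.47 ± 0.90, adjusted p = 0.0395), a call lost with the block (3.17 ± 0.84, adjusted p = 0.874) and in 25 of 53 fits with 1 library left out. Voom called none of the 5 (adjusted p = 0.163 for Xist and 0.514 for Ddx3y, Eif2s3y, Uty and Kdm5d). The block gave 6 genes, among them the predicted gene Gm29650 (log2 -4.01 ± 0.77) next to Eif2s3y and, as the single autosomal call, Gata3 (-3.74 ± 0.71, adjusted p = 0.0313), at 0.0289 CPM in libraries labelled female and 0.157 CPM in those labelled male. Gm29650 and Gata3 were chosen after their values were seen. The 6 libraries whose sex-linked genes go against the label are among those averaged.

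At single ages few genes passed between the labelled sexes. At P7, 4 genes were lower in libraries labelled female, namely Pvalb (0.949 against 21.3 CPM, log2 -4.85 ± 0.90), Tnni1 (-4.50 ± 0.89), Gm13446 (-4.88 ± 0.96) and 0610043K17Rik (-4.52 ± 0.88), each with adjusted p = 0.0399 and chosen after its values were seen. None passed with the block. The level of Pvalb was 82.6 CPM in P7 male 6 and at most 2.09 CPM in each of the other 11 libraries of this age. Without P7 male 6 no gene passed, and the same was the case without P7 male S1 or any of P7 females 10, 30, 40, 6, S1 and S2, while 2 genes were left without P7 female 4 and 8 without P7 male 2. At P1, P4, P14, P35 and in adults no gene passed in edgeR, with 769, 237, 361, 332 and 310 genes at an unadjusted p under 0.05. At P1, Eif2s3y missed the threshold though it was at least 1470-fold lower in females, against a floor of 3 counts over 4 libraries. The smallest adjusted p at P1 was 0.193 in edgeR. Recovery was not simulated for sex differences, so the lack of calls does not show that the sexes were alike at these ages. DESeq2 called 48, 1, 4, 1 and 2 genes at these ages, and voom called 1 at P4 and none at the rest. Without P1 female 6 there were 9 calls at P1, and 5 without P1 female 1 or P1 female 3.

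The Y-linked genes moved as a list at P14 (5 of 5 lower adjusted over the list alone, adjusted p = 1.06e-21, and 0.000469 with an estimated correlation). Eif2s3y was at least 1240-fold lower there, against a floor of 3 counts over the 5 libraries labelled female. The X-linked genes known to escape silencing, with Xist, had a median of 0.51 there (adjusted p = 9.39e-07, 0.0108 with an estimated correlation, and 0.101 without P14 male 4). As a mean over the ages the Y-linked genes had adjusted p = 3.32e-06 with an estimated correlation. In adults they had a median of -4.42 (adjusted p = 1.02e-10, 0.0209 with an estimated correlation and 0.101 with that estimate and the block), and the estimate missed the threshold without any of adult males 1, 2, 3 and 4 and adult females 1, 2, 3 and 4 (highest 0.478). The immediate early genes of adults had a median of -0.62, lower in libraries labelled female, with no member past the threshold (adjusted p = 3.65e-12, 0.0209 with an estimated correlation and 0.101 with that estimate and the block). The scores of this list were 4.02 ± 0.71 (n = 4) in adults labelled female and 4.68 ± 0.78 (n = 5) in those labelled male, or 4.46 ± 0.70 (n = 4) without adult male 60, whose sex-linked genes go against the label. The median was -0.36 without adult male 60, -0.35 without adult female 1 and -1.06 without adult female 3, and the estimate missed the threshold without adult male 3 (0.0847), 4 (0.119) or 60 (0.546) or adult female 1 (0.864), 2 (0.0710) or 4 (0.0579).

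At P7 the oligodendrocyte and myelin markers had a median of -1.53 (adjusted p = 2.98e-16, and 0.103 with an estimated correlation). Without P7 male 6 the median was -0.49 (adjusted p = 0.00586), and the mean score of males at this age fell from 2.72 to 2.02, against 1.53 in females. Without P7 male S2 the estimate passed (0.0285). With the 11 doubtful libraries left out and the block in the fit, the calls at single ages were Xist and Y-linked genes alone, for example Kdm5d at P14 (log2 -6.29 ± 1.00). Of these 11 libraries, 6 were left out by the same genes, so the direction of those calls is no independent evidence.

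Whether a step differed between the sexes was tested by interaction terms, and no gene passed in any of them. Recovery was not simulated for these terms, so the lack of calls does not show that the steps were alike. The counts at an unadjusted p under 0.05 in edgeR were 372 for P1 to P4, 389 for P4 to P7, 622 for P7 to P14, 344 for P14 to P35, 397 for P35 to adult and 353 for all steps in 1 test, and none passed with the block. DESeq2 called 3, 1, 8, 2, 1 and 3 genes and voom none. The immediate early genes had a median of -1.42 in the interaction from P35 to adult (adjusted p = 2.48e-14, 0.0141 with an estimated correlation and 0.0643 with that estimate and the block), and no member passed. The estimate missed the threshold without P35 male 1 (0.0562), P35 male 10 (0.0756) or P35 female 3 (0.0826), and the median was -2.36 without P35 male 3. Their scores were 5.11 ± 0.37 (n = 3) at P35 and 4.02 ± 0.71 (n = 4) in adults labelled female, and 4.26 ± 0.87 (n = 3) and 4.68 ± 0.78 (n = 5) in animals labelled male. In the interaction from P7 to P14 the oligodendrocyte and myelin markers had a median of 2.08 (adjusted p = 5.19e-17, and 0.0770 with an estimated correlation), with P7 male 6 and P14 male 6 among the libraries compared. Without P7 male 6 the median was 0.89, and the estimate passed without P14 female 1 (0.0303), P7 male 2 (0.0488), P14 male 3 (0.0446) or P7 male S2 (0.0376).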

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

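The tests of cell type lists between description numbers, of library size for number 3 and the second run, of the labels at P7, P35 and in adults, of the exchanged ages and of other splits of the libraries were chosen after the results were seen, while the test of library size for number 6 and both tests at P4 were fixed before.

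Libraries of number 6, 3 and the second run had higher neuronal and lower mature astrocyte markers than number 1. If RNA of all other cell types stood in place of astrocyte RNA and raised their scores alike, the scores would move together. The neuronal score rose by 1.48 ± 0.24 (SE, log2) more than the mean score of the 7 lists of other cell types in number 6. The gap was 1.14 ± 0.20 in number 3 and 1.87 ± 0.33 in the second run. The other lists have lower scores, where the prior count shrinks changes, and equal rises were assumed. These gaps therefore cannot decide against RNA of all other cell types. Single lists rose too, such as red blood cell markers in number 6 (1.65 ± 0.26 against 1.80 ± 0.15 for the neuronal score) and, in number 3, endothelial and mural markers (1.25 ± 0.26) and oligodendrocyte and myelin markers (0.94 ± 0.38), so RNA of some other cell types besides neurons stays open. Library size as the whole cause is argued against, since the neuronal term of number 6 was 1.81 with the log2 total count in the model and 1.80 without it. That of number 3 was 1.74 and 1.75, and that of the second run 1.60 and 1.67. More neuronal RNA in these libraries stays open as a candidate explanation that no test here decides, since the share of called neuronal members that were higher in numbers 6 and 3 (100%) only restates the pattern. What the number stands for is not given in the sources used here, and no biological explanation was tested.

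Sex-linked genes went against the label in 6 libraries. At P4, an exchange of the whole libraries P4 female 2 and P4 male 4 is only weakly argued against. Of the 2, 2 correlated better with libraries of their own number (0.48 ± 0.08 against 0.27 ± 0.06, and 0.35 ± 0.04 against 0.12 ± 0.07, SE), which a wrong sex noted for both animals allows. The differences were 0.2 ± 0.1 and 0.24 ± 0.07. These SEs are over correlations that share the tested library and so are not independent. At P7, an exchange between the groups may account for P7 female S2 and P7 male S2, since both of these 2 libraries of the second run, 1 of each label, went against their label. At P35 and in adults an exchange between the groups is argued against by a highest Y-linked level of 7.96 CPM in libraries labelled female, and a single wrong label in each group stays open, with the letter of the other sex in the description names of 2 of 2 libraries. P35 male 10 correlated at only 0.02, 0.07, 0.08 and 0.05 with adult male 1, P14 male 1, P4 male 1 and P1 female 1. With other libraries of number 1 from different groups it correlated at 0.1 or more, and the median over pairs within a level was 0.49. Adult male 60 fell below 0.1 with P1 female 6 alone (0.09). Whether P35 male 10 is a library of number 1 thus stays open. Biological differences between animals were not tested.

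The age-dependent genes of P7 male 6 and P14 male 6 looked exchanged. Of the 123 genes called from P7 to P14 in animals labelled female, 4.07% changed the same way from P7 male 6 to P14 male 6, against 100% from P7 male 2 to P14 male 2. P14 male 6 lay nearer the other P7 males in 91.1% of these genes, which an animal ahead of its age at P7 alone would not give. Those P7 males carry number 2 or the second run and the other P14 males numbers 1, 2, 3 and 4. Part of the share may thus follow the description number, so it does not decide this. Within number 6, the cell cycle score was 3.55 in P14 male 6 and 1.64 in P14 female 6. Library size is argued against, in 60 genes called without P7 female 6 and P14 female 6. Of these, 98.3% changed the same way from P7 female 6 to P14 female 6 and 100% from P7 male 2 to P14 male 2, though both P7 libraries had totals near that of P7 male 6. An exchange of the 2 libraries stays open as a hypothesis, and the calls at P7 between the sexes and from P4 to P7 in males rest on P7 male 6 in part. Both libraries also enter the step from P7 to P14 in males, where the lack of calls is no evidence of a smaller change than in females.

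Further libraries stood apart from their group, adult male 60 in 3 measures, P1 male 1 and P7 female 40 in 2 and others in 1, by a gap to the nearest other library that is large for the range of the group. Of 110 groups and measures tested, 21 gave such a library, where independent and normally distributed values would give about 5%. Levels of sex-linked genes are not so distributed, and libraries against their label are among them. The measures were also taken on the same libraries, so the 5% is no measure of chance here. Genes with at least 10 counts numbered 17320 in adult male 3 (16338 to 16619 in the others) and 10085 in P1 female 4 (16562 to 17665). The 100 largest genes took 38.3% of counts in P14 male 4 (15.2 to 19.1% in the others) and 21.4% in P7 female 40 (17.3 to 19.2%). Aldh1l1 stood at 40.2 CPM in adult male 60 (199 to 260 in the others) and 377 CPM in P1 male 1 (121 to 153). Xist stood at 3.33 CPM in adult male 60, 10.6 in P4 male 4 and 20.7 in P7 male S2, all labelled male, and at 125 CPM in P7 female 3, 101 in P1 female 3 and 123 in P4 female 3. The Y-linked sum stood at 194 CPM in P7 female S2, 60.8 in P4 female 2 and 0.687 in P14 female 3. The mature astrocyte score was 6.61 in adult male 60 (8.61 to 9.32 in the others), 6.21 in P14 female 6 (8.37 to 8.77) and 7.66 in P1 female 1 (4.68 to 5.09). The oligodendrocyte and myelin score was 1.82 in P1 male 1 (0.69 to 0.88), the cell cycle score 1.96 in P7 female 40 (3.31 to 4.23) and the immediate early gene score 4.29 in P14 male 3 (3.67 to 3.82). Adult male 60 and P14 female 6 carry number 6, in which 28 of 28 mature astrocyte markers were lower than in number 1, that of P1 female 1. The libraries labelled female with the high Xist values carry number 3, whose range was 11.8 to 125 CPM. Part of these gaps may thus follow the description number.

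The step from P35 to adult differed between the labelled sexes for the immediate early genes, with adjusted p = 0.0141 with an estimated correlation in the interaction test and 0.0643 with the block. No single gene passed there. The estimate was 0.0756 without P35 male 10, whose sex-linked genes go against the label, 0.0562 without P35 male 1 and 0.0826 without P35 female 3. Animals labelled female at P35 carry the description numbers 3, 4 and 6 and those labelled male 1, 1 and 3, and against number 1 these genes were higher in 14 of 25 in number 3 and in 10 in number 6 (4 lower in each), and in 5 in number 4 (0 lower). In number 3, 11183 of 21118 genes passed, and the list had adjusted p = 0.0969 by camera (0.798 with an estimated correlation), so its count is not specific to the list. At the preset correlation the list passed in number 6 (adjusted p = 0.00454, with 7240 genes past the threshold). It also passed in number 4 (0.00288, with 3771 genes). With an estimated correlation it passed in neither (0.329 and 0.367). The description number stays open as part of this difference.

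Other splits of the same libraries into groups of the same sizes were fitted to count how often they call as many genes, for single ages and steps and for P1 to adult with the compared groups alone, so that some counts of the labels differ from those of the report. For the sex difference at P14, 3 of 100 splits gave as many genes as the labels (4, highest other split 1710), and as a mean over the 6 ages 1 of 30, that of the labels (5, highest other 0). From P7 to P14 in females 3 of 100 gave as many (133, highest other 3457), and from P1 to adult 1 of 100 (4286, highest other 1307). Over all splits drawn, these 4 shares were under 0.05, unadjusted for the number of comparisons. Splits differ in how many pairs of the same description number they part, so these shares alone do not exclude chance. At P14 edgeR called 0 genes with all groups in the fit, with or without the block, so no sex difference at P14 rests on this. For the sex difference at P1, 2 of 35 splits gave as many (2, highest other 309), and chance cannot be excluded. Where the labels called 0 genes, all splits give as many by construction, which says nothing about chance. Between the sexes this was so at P4 (35 splits, highest other 3068), P7 (100 splits, 4158) and in adults (100 splits, 2894). In males it was so from P1 to P4 (35 splits, highest other 1), P4 to P7 (35 splits, 3066), P7 to P14 (100 splits, 1325), P14 to P35 (56 splits, 2489) and P35 to adult (56 splits, 4778), and in females from P1 to P4 (35 splits, 9), P4 to P7 (100 splits, 1768), P14 to P35 (56 splits, 1648) and P35 to adult (35 splits, 3840).

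The interactions, with sex exchanged within each age, called 0 genes with the labels and as many in all 30 splits, with 6 as the highest other from P7 to P14 and 0 in the steps from P1 to P4, P4 to P7, P14 to P35 and P35 to adult and for any age, which again says nothing about chance. For the sex difference at P35 the 10 splits are too few for a share under 0.05, with 0 genes by the labels and 2145 in the highest other split. Splits that call many more genes than the labels point to a structure of the libraries. The highest splits at single ages and steps and from P1 to adult part fewer pairs of libraries of the same description number than the labels do. Among splits that part as many such pairs as the labels, the highest count was 0 apart from 197 from P7 to P14 in males. From P7 to P14 in females there were 37 such splits, while the 14 at P14 between the sexes and the 2 from P1 to adult are too few for a share under 0.05 by this narrower count, which was not run for the mean over the ages. With the block the labels gave 6 genes for the sex difference as a mean over the ages, 1149 from P7 to P14 in females and 8718 from P1 to adult.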

How the results depend on the processing

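Chosen after the data were examined were the fits without the 6 libraries whose sex-linked genes go against the label, without P7 male 6 and P14 male 6, without the 3 libraries with the fewest genes, with 3 levels of run, with a minimum mean of 1 CPM, and with the block and all 11 of these libraries left out. The planned variants that sum the runs of the animals sequenced in 2 runs, put the second run in place of the first or use second runs alone were not run, since each of these animals has 1 column here. Taking away the filter on low counts moved nothing, because it removed no gene, and so says nothing about stability. Followed in the alternatives were genes named by the size of the fold change and called sex chromosome genes. List members past the threshold from P1 to adult and from P7 to P14 in females were followed too. None of these changed direction, which their choice by the threshold made likely in advance and so says little about stability. Gata3, the calls at P7 between the sexes and other genes chosen after their values were seen were not followed, apart from Gm29650. Over the followed genes, 2588 values kept their side of the threshold with 1 library left out, 151 lost it and 11 gained it. In the other settings 2320 kept it, 86 lost it and 60 gained it. Of these 2320 values, 165 come from the fit without the low-count filter, which kept them by construction. Xist as a mean over the ages lost its call in 25 of the left-out fits. What changed most was the number of genes called, and the cause was not tested except where fewer libraries or genes entered by construction. P14 male 4 had the lowest total (14768178 counts) and P1 female 4 the fewest genes at 10 counts or more (10085), and depth was not tested as the cause of any change.

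With the replicate block, which pairs libraries by description number, the counts were 0 for the sex difference at P7 (4 without it), 20 from P1 to P4, 15 from P4 to P7 and 8 from P14 to P35 in males, and 1149 from P7 to P14 and 2 from P14 to P35 in females, and P1 to adult gave 8718 against 5926. Of the gene lists, 207 in place of 258 of 690 tests passed. As a mean over the ages the sex difference gave 6 genes against 5, and in the other comparisons the count stayed at 0 with the block. Over the followed genes the block kept 145 values on their side of the threshold, gained 19 and lost 1, that of Xist. With the block and the 11 libraries left out, the sex difference gave 4 genes at P1, 2 at P4, 3 at P7, 5 at P14 and 3 in adults, the steps in males gave 260 from P1 to P4, 0 from P4 to P7, 96 from P7 to P14 and 0 from P14 to P35, those in females 3407 from P7 to P14, 18 from P14 to P35 and 1 from P35 to adult, and P1 to adult gave 9955.

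DESeq2 called 48, 1, 11, 4, 1 and 2 genes between the sexes at the 6 ages, 1, 90, 1 and 14 in the first 4 steps of males, 21, 4, 537, 10 and 2 in the 5 steps of females, and 3, 1, 8, 2 and 1 in the interactions of the 5 steps, with 3 for all steps in 1 test. Voom with quality weights called 1 gene between the sexes at P4, 0 at P7 and 0 as a mean over the ages, 435 from P1 to P4, 138 from P4 to P7, 146 from P14 to P35 and 81 from P35 to adult in males, 1439 from P7 to P14 in females and 9459 for P1 to adult, mean of the sexes. With the compared groups alone in the fit there were 2 genes between the sexes at P1, 0 at P7 and 4 at P14, and 0 from P4 to P7 in males. With DESeq2 size factors 2 genes passed from P4 to P7 in males, and with a minimum mean of 1 CPM 8. With the correlation estimated per list, 14 list tests passed in place of 258.

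The sex difference at P7 fell from 4 genes to 0 without the run term, with first-run libraries alone, without the 5 libraries of the other description letter, without P7 male 6 and P14 male 6, without the 3 libraries with the fewest genes and with 3 levels of run. Without the 6 libraries against their label it gave 1 gene, with 4 at P1 and 3 at P14. From P4 to P7 in males the counts in these settings were 0, 1, 9, 0, 29 and 0, and 0 without the 6 libraries. From P7 to P14 in females they were 367 without the run term, 3 without the 5 libraries, 275 without P7 male 6 and P14 male 6, 314 without the 3 libraries with the fewest genes and 13 with 3 levels of run. From P14 to P35 in females 1 gene passed without the 3 libraries.

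With each library left out in turn, the counts ran from 0 to 9 for the sex difference at P1, from 0 to 8 at P7, from 4 to 6 as a mean over the ages, from 0 to 58 from P4 to P7 and from 0 to 1 from P14 to P35 in males, from 14 to 155 from P7 to P14 and from 0 to 1 from P14 to P35 in females, from 5285 to 6113 from P1 to adult, and from 0 to 1 for the interaction from P7 to P14, where the 1 came without P7 male 2. The 1 from P14 to P35 came without P14 male 3 in males and without P14 female 2 in females. In the other comparisons it stayed at 0 throughout. Of the 258 list calls, 106 kept an adjusted p under 0.05 at the preset correlation with any library of the compared groups left out.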

Other observations

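The gene lists below were fixed before the data were examined, while the comparison of Xist between description numbers was chosen after its values were seen.

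In 5 lists of secreted factors, phagocytosis, interferon response, FGF signalling and steroids, more members rose than fell between P1 and adulthood. Of 21 synaptogenic and synapse regulating secreted factors, 6 rose and none fell (6 adjusted over the list alone, median log2 change 0.57, or 0.37 without adult female 1, camera adjusted p = 0.00878, and 0.351 with an estimated correlation). Il33, a cytokine that astrocytes release, went from 3.87 ± 4.61 CPM (SD, n = 8) to 104 ± 34.2 CPM (n = 9), a log2 change of 4.71 ± 0.67 (SE), and Sparcl1, which promotes synapse formation, from 156 ± 118 to 699 ± 264 CPM. Of 17 phagocytic pathway genes, 3 rose and none fell (7 with the block, adjusted p = 0.0245, and 0.575 with an estimated correlation), with Mertk, a receptor for engulfment, from 2.70 ± 2.50 to 32.7 ± 15.6 CPM, Gas6 (log2 1.53) and C4b (2.41). Of 24 genes of interferon and antigen presentation, 11 rose and none fell (13 and 1 adjusted over the list alone, 12 and 1 with the block, median 1.27, adjusted p = 2.32e-05, and 0.156 with an estimated correlation), such as B2m from 44.0 ± 22.5 to 142 ± 51.1 CPM and Ifit3 (log2 3.77), whose reads are uncertain beside its near copy Ifit3b. In FGF signalling 7 of 23 rose and 2 fell (median 0.54, or 0.86 without P1 female 1, adjusted p = 0.0244, 0.0516 without P1 female 4, and 0.367 with an estimated correlation), with Fgf1 from 17.9 ± 28.3 to 212 ± 107 CPM and its receptor gene Fgfr3 from 44.3 ± 42.2 to 182 ± 97.0 CPM. Of 22 genes of sex steroid receptors and steroid metabolism, 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.29, or 0.64 without P1 male 3, adjusted p = 0.0361, and 0.331 with an estimated correlation), a call lost without adult female 1 (0.0519), P1 female 1 (0.0520), P1 female 4 (0.0545) or P1 male 2 (0.0546). Hsd11b1, which regenerates active glucocorticoid, went from 1.99 ± 1.88 to 34.5 ± 22.1 CPM (4.28 ± 0.59).

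Other lists split or stayed short of the threshold over the same span. In Notch, BMP and JAK-STAT signalling 4 of 31 rose and 7 fell (10 and 9 with the block, median 0.46, adjusted p = 0.882), with Cntfr up (log2 2.13) and Nfib down (-1.33). Of 27 genes of extracellular matrix and proteoglycans, 3 rose and 5 fell (6 and 8 with the block, median -0.51, adjusted p = 0.654), with Timp4 up (2.94). Of 37 reactive astrocyte genes, 8 rose and 7 fell (median 0.28, adjusted p = 0.882), with Hspb1 up (1.89) and Vim down (-1.53). Among other cell types, oligodendrocyte precursor markers had 4 of 16 up and 2 down (7 and 3 with the block, median 0.67, adjusted p = 0.654), with Neu4 at 3.48 and Cacng4 at -2.52, and endothelial and mural markers had 3 of 21 up and 1 down (4 and 3 with the block, median 0.03, adjusted p = 0.913), with Ly6c1 at 2.50 and Cldn5 at -1.17. In choroid plexus and ependymal markers 3 of 12 rose and 2 fell (median 1.15, adjusted p = 0.913), with Enpp2 at 2.46 and Foxj1 at -2.33. Of 14 meningeal fibroblast markers, Col3a1 fell (log2 -2.73), and 2 fell with the block, with a median of -0.10 and adjusted p = 0.760 for the list. The 7 red blood cell markers had a median of -0.17 (adjusted p = 0.654). Without the block no member passed among the 5 Y-linked genes (median 1.91, adjusted p = 0.760) or the 11 X-linked genes known to escape silencing, with Xist (median -0.13, adjusted p = 0.654), of which 2 fell with the block.

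Xist, an RNA that stays in the nucleus, varied among libraries labelled female with the description number. In number 3 it stood at 101 CPM at P1, 123 at P4, 125 and 47.2 at P7, 51.6 at P14, 108 at P35 and 11.8 in adults. Libraries labelled female of number 1 held from 3.75 to 6.33 CPM and those of number 4 from 0.0621 to 10.9 CPM, while those of number 6 lay between 2.90 and 7.99 CPM up to P14 and higher at P35. In number 2, P14 female 2 held 37.7 and adult female 2 held 26.5 CPM, and P4 female 2 had no count. No test was run on these values.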
